A study of Cannabis sativa with 4 samples.

How the data were processed

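RNA was measured in flowers of 2 hemp cultivars at 2 stages, with total RNA and 1 library per group, 4 libraries in all. Reads were trimmed with Trimmomatic 0.36 and compared with DESeq 1.36.0, per the submitters' processing notes. The aligner, the genome build and the annotation behind the transcript models were not given in the sources used here. The 4 deposited tables each held the same 36241 transcript models and the same 4 library columns.

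The signal values of each library are read counts that the authors divided by a DESeq size factor before they were deposited, per the file headers and the processing notes. The deposited fold changes are the authors' ratio of normalized counts, late over early or Lim over Amb, for 1 library against 1. The deposited log2 values are the authors' log2 of that ratio without a pseudocount. The deposited p-values and adjusted p-values are those the authors obtained with DESeq from 1 library against 1. A further 12 columns with values per sample were not used. Descriptions are the deposited best hits; 2953 models had none, 603 of them among the kept models, and 14839 kept models had a named description. A reference table of gene names from another hemp genome assembly matched 11925 kept models by best hit and served for names only.

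Normalized values were multiples of a step per library, 0.858 in ES-Amb, 0.821 in ES-Lim, 1.12 in LS-Amb and 1.24 in LS-Lim, so that whole reads were recovered for 100% of the values at a tolerance of 0.05. The recovered depth was 40088937 to 51447465 reads per library. Models above 0 numbered 15637 in ES-Amb, 15877 in ES-Lim, 15732 in LS-Amb and 15620.0 in LS-Lim, and 18508 models were at 0 in all 4. Models with a normalized value of at least 1 in 1 or more libraries were kept, 17154 in number. Log2 ratios were taken of the deposited values with a pseudocount of 1. Intervals of folds hold 95% for counting error of the recovered reads, and the spread between plants is in none of them. A fold against 0 reads is given as a bound at 3 reads, and no fold is given where both libraries were at or under 3 reads. The fitted log2 change of a model at 0 depends on the pseudocount and is no bound.

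For stage and for cultivar an additive model with both factors was fitted with limma 3.58.1 in R 4.3.3 to log2 of the value plus 1, for 15694 models with a value of at least 1 in 2 or more libraries, with a trended prior (2.43 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. The design named edgeR for deposited counts and limma for deposited normalized values, and limma was used; edgeR 4.0.16 on the recovered reads (common dispersion 0.199) was added as an alternative, and DESeq2 1.42.0 and limma-voom were run as well. The choices written for CPM (reads scaled by library total), a pseudocount of 0.25 and a minimum of 10, were applied on the normalized count scale, which differs from CPM by a factor per library. Size factors computed with DESeq2 gave the deposited scaling again, so TMM and total count scaling were the other scalings.

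The comparisons, the 33 gene lists, the rule for named genes and most alternative settings were written before the data were examined. Lists were formed by matching words in the descriptions. After the matches were read, words matched inside longer words were left out, 211 models from the transporter list, 12 from AP2/ERF factors, 9 from ethylene and 33 from the cell cycle list (RNA-directed DNA polymerases). With the lists as first written camera called 11 of 33 for stage, as with the lists used. Each list median is described by its percentile among 10000 random lists matched on mean expression, and tested with camera (preset and estimated correlation) and fry. Further lists were added after the highest and lowest models had been seen: a second embryo list, abscisic acid genes without embryo proteins, tapetum and pollen wall genes, and pathway genes that the cannabinoid list had missed. The second embryo list also caught GEM-like proteins and 2-isopropylmalate synthases by their wording.

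Genes were named by a fixed rule. It took (a) every kept cannabinoid list member, (b) for each pairwise comparison the 8 highest and 8 lowest log2 ratios with a named description and at least 20 in the higher library, 1 per description, (c) for each other list the 2 to 4 members with the highest mean, and (d) for each additive test the 10 largest folds in each direction past the threshold. The text gives a selection of these. Other genes are said to be chosen after their values were seen.

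The steps were tested on simulated data. Planted folds were placed only in models above a minimum mean level, so recovery among low models was not tested. With counting error alone, all 100 planted 4-fold and all 100 planted 16-fold differences were found in each pairwise comparison, intervals covered the truth for 90 to 98 of 100, and 548 to 1114 unchanged models of 17154 passed 2-fold. For the additive model at a dispersion of 0.1, limma recovered 74% of 4-fold stage and 72% of 4-fold cultivar differences among 15383 and 15380 models, edgeR 72% and 69%, and each recovered 100% at 16-fold; limma called 16 and 7 unchanged models. At a dispersion of 0.2, simulated after the results were seen, limma recovered 25% and 24% of 4-fold stage and cultivar differences among 15374 and 15375 models, and edgeR 17% and 14%. For 16-fold stage and cultivar differences at that dispersion limma recovered 100% and 98%, and edgeR 98% and 96%. Of 240 percentiles of random lists, 232 (96.7%) lay within the central 95%. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.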

Results

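RNA was sequenced from flowers of hemp (Cannabis sativa) plants that grew untreated in a greenhouse. The 4 libraries came from 2 cultivars, CBG-Ambit (Amb) and CBG-Lim (Lim), each at an early stage (ES) and a late stage (LS). Each group had 1 library, so no value has a spread between replicates. In the fits over all libraries the stage by cultivar difference, with information shared across models, stood for the error. Their SE and p-values therefore hold no spread between plants. Reads recovered from the normalized counts numbered 48714348 in ES-Amb, 51447465 in ES-Lim, 42999299 in LS-Amb and 40088937 in LS-Lim. The 10 most abundant transcript models took 4.04% of the normalized counts in ES-Amb, 4.89% in ES-Lim, 6.88% in LS-Amb and 7.56% in LS-Lim. Of 36241 transcript models, 17154 had a normalized count of at least 1 in 1 or more libraries. Levels are normalized counts, folds carry a 95% interval for counting error only, and a fold against 0 reads is a lower bound set at 3 reads in that library (2.58 normalized counts in ES-Amb, 2.46 in ES-Lim, 3.35 in LS-Amb and 3.72 in LS-Lim).

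The first comparison asked which transcripts differed between early and late flowers of both cultivars, with cannabinoid synthesis as the pathway of interest. The transcript of a cannabidiolic acid synthase precursor (evm.model.09.1091), the enzyme type that turns cannabigerolic acid into cannabidiolic acid, was scarce early and abundant late. Its level was 12.9 in ES-Amb and 33.6 in ES-Lim against 10235 in LS-Amb and 17192 in LS-Lim, a rise of 9.24 on the log2 scale (SE 0.33, limma adjusted p = 0.023). A tetrahydrocannabinolic acid synthase-like model (evm.model.09.797), of the same oxidocyclase family, rose by 3.03 (SE 0.29, limma adjusted p = 0.027), from 202 and 164 in the early libraries to 1691 and 1322 in the late ones. A geranylpyrophosphate:olivetolate geranyltransferase-like model (novel_model_1814_5bd9a17a) rose by 1.85 (SE 0.15, limma adjusted p = 0.024), from 2675 and 2030 to 8706 and 8154.

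Of the 10 models in the cannabinoid pathway list, 4 rose and 0 fell, and the same number, 4, passed when adjusted over the list alone. The remaining one that rose was cannabidiolic acid synthase-like 1 (evm.model.09.1318), by 5.36 (SE 0.91, limma adjusted p = 0.048), which edgeR placed at an adjusted p of 0.079. Its early levels were 0.858 and 4.92 and its late levels 146 and 125. The list had a median of 0.71 and a camera adjusted p of 0.197, with adjusted p = 0.53 with an estimated correlation. Among the models that did not pass, the geranyltransferase annotated as prenyltransferase 4, the enzyme that makes cannabigerolic acid (evm.model.01.1974), stood at 1359 in ES-Amb, 654 in LS-Amb, 564 in ES-Lim and 600.1 in LS-Lim. A 2-acylphloroglucinol 4-prenyltransferase (evm.model.01.1278) stood at 262 and 316 early and at 44.7 and 117 late. Olivetolic acid cyclase, which folds the polyketide into olivetolic acid, was represented by a model (novel_model_6008_5bd9a17a.2.5bd9b13b) listed at 1.72 and 9.03 early and at 0 in both late libraries. The model name carries an isoform suffix. Of loci with such a suffix or with 2 or more models, 92.6% were under 100 in every library. Oxidocyclases and aromatic prenyltransferases are close in sequence and could share reads, so the split of reads among their models is uncertain.

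**Figure D1:**
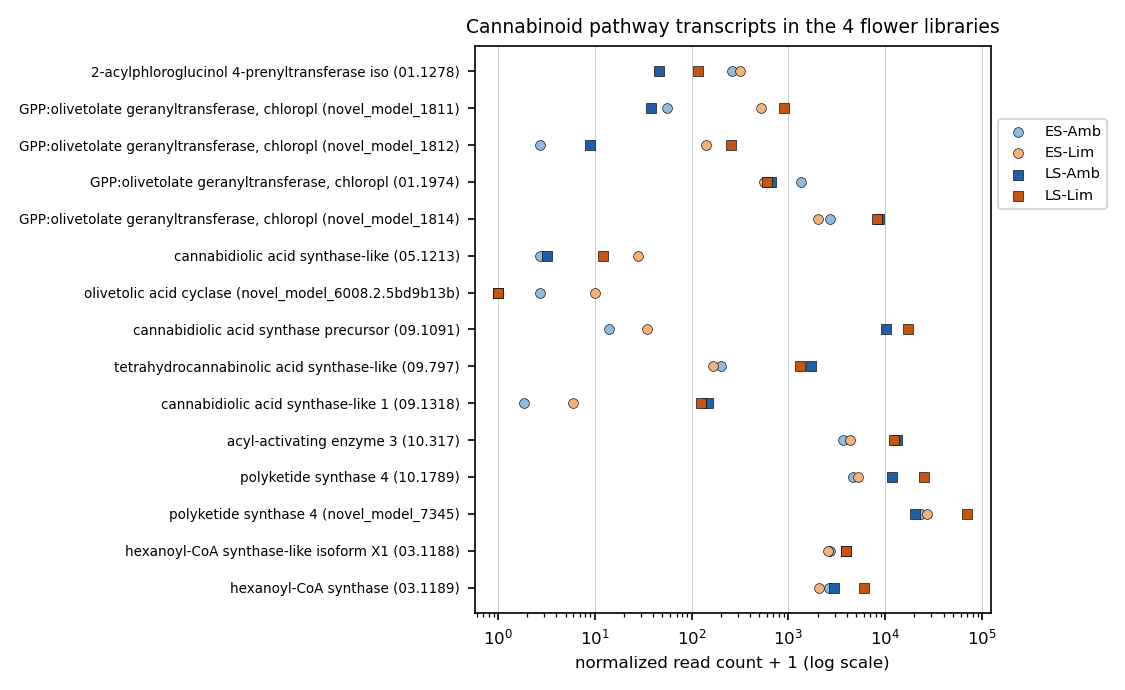
Levels of the 10 cannabinoid pathway models and of 5 further pathway models in each library. The x axis is the normalized read count plus 1 on a log scale, each line is a transcript model, circles are ES, squares are LS, blue is Amb and orange is Lim; the cannabidiolic acid synthase precursor goes from 12.9 and 33.6 early to 10235 and 17192 late.

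Earlier steps of the pathway were read from 5 models that were chosen after their values were seen. An acyl-activating enzyme 3 (evm.model.10.317), of the family that makes acyl-CoA starters, rose by 1.69 (SE 0.15, limma adjusted p = 0.026). A polyketide synthase 4 (evm.model.10.1789), of the type III polyketide synthase class, rose by 1.79 (limma adjusted p = 0.045, edgeR adjusted p = 0.065). A second polyketide synthase 4 model (novel_model_7345_5bd9a17a) did not pass, with 23465 in ES-Amb, 20365 in LS-Amb, 26702 in ES-Lim and 70144 in LS-Lim. Hexanoyl-CoA synthase-like evm.model.03.1188 went from 2671 and 2541 to 3914 and 3917, and hexanoyl-CoA synthase evm.model.03.1189 from 2604 and 2047 to 2957 and 6038, and neither passed.

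Of 12 models of the plastid methylerythritol phosphate (MEP) pathway, 1 rose and 0 fell, 0 when adjusted over the list alone; it was a 4-hydroxy-3-methylbut-2-en-1-yl diphosphate synthase (evm.model.06.2005), by 0.78 (SE 0.14), which edgeR placed at an adjusted p of 0.076. The most abundant member, a probable 1-deoxy-D-xylulose-5-phosphate synthase (evm.model.07.552), which starts the pathway, stood at 26734 and 20539 early and at 38549 and 24878 late. Of 8 mevalonate pathway models, 1 rose, acetyl-CoA acetyltransferase 1 (evm.model.02.2743), by 2.04 (SE 0.17, limma adjusted p = 0.024), and 2 passed when adjusted over the list alone. The 3-hydroxy-3-methylglutaryl-coenzyme A reductase evm.model.01.168, the rate-limiting step of that pathway, stood at 1468 in ES-Amb, 9643 in LS-Amb, 8831 in ES-Lim and 23007 in LS-Lim (limma adjusted p = 0.054). Of 4 prenyl diphosphate synthase models 1 rose, and 1 passed when adjusted over the list alone. Of 17 terpene synthase models 1 rose and 1 fell, 2 when adjusted over the list alone. Terpene synthase 32 (evm.model.07.849) fell by 2.82 (SE 0.20, limma adjusted p = 0.023), while terpene synthase 29 (evm.model.10.1522), at 717 and 82.9 early against 2395 and 1251 late, did not pass.

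Several flavonoid transcripts were lower late. Naringenin-chalcone synthase (evm.model.07.160), the entry enzyme of flavonoid synthesis, fell by 2.43 (SE 0.20, limma adjusted p = 0.024), from 62086 and 64471 to 14053 and 9837. Dihydroflavonol 4-reductase (evm.model.03.481), which leads toward anthocyanins, fell by 2.31 (SE 0.13, limma adjusted p = 0.023). The type III polyketide and flavonoid list matched flavonoid words such as chalcone and naringenin, and the polyketide synthase 4 models lie outside it. Of its 54 models 6 rose and 12 fell, 20 when adjusted over the list alone. The median was -0.44 and the mean was 0.13. The limma camera test of that list pointed down (adjusted p = 0.187). Of 56 phenylpropanoid and lignin models 12 rose and 4 fell, 26 when adjusted over the list alone. Among them trans-cinnamate 4-monooxygenase (evm.model.06.1713) rose by 1.18 and a probable cinnamyl alcohol dehydrogenase 1 (evm.model.05.2137) by 0.93, which edgeR placed at adjusted p-values of 0.072 and 0.054, while phenylalanine ammonia-lyase evm.model.03.658 stood at 20405 and 23113 early and at 9429.9 and 18261 late without passing.

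Lipoxygenase 2 (evm.model.06.2046), a chloroplast enzyme that feeds jasmonate and green leaf volatile synthesis, rose by 2.14 (SE 0.23, limma adjusted p = 0.030), from 25907 and 12298 to 90291 and 68226. Fatty acid hydroperoxide lyase (evm.model.10.1437), which makes green leaf volatiles, rose by 1.25 (SE 0.13, limma adjusted p = 0.030). Of 48 lipoxygenase and jasmonate models 7 rose and 1 fell, 8 when adjusted over the list alone. Of 54 fatty acid synthesis and desaturation models 8 rose and 8 fell, 18 when adjusted over the list alone; the oleate desaturase FAD2 (evm.model.10.481) fell by 1.01 (edgeR adjusted p = 0.059) and the peroxisomal 3-ketoacyl-CoA thiolase 2 (evm.model.07.157), an enzyme of fatty acid breakdown, rose by 1.66. Of 125 cuticle, wax and lipid transfer models 10 rose and 16 fell, 43 when adjusted over the list alone. Non-specific lipid-transfer protein 2 (novel_model_6087_5bd9a17a) rose by 3.08 to 169790 in LS-Amb and 84349 in LS-Lim, and the GDSL esterase/lipase LTL1 (evm.model.06.431) fell by 3.41, each with an edgeR adjusted p of 0.054.

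Cell division transcripts were the group furthest below their early level. Histone H3.2 (novel_model_5927_5bd9a17a), a core histone made during DNA replication, fell by 4.86 (SE 0.21, limma adjusted p = 0.023), from 38868 and 32895 to 1076 and 1415. A probable histone H2B.1 (evm.model.06.907) fell by 1.82 (SE 0.17, limma adjusted p = 0.026), while histone H4 (evm.model.06.1922), at 44515 and 37014 early against 7045 and 21291 late, did not pass. Of 178 cell cycle and chromatin replication models 5 rose and 76 fell, 113 when adjusted over the list alone, with a median of -2.08 and a camera adjusted p of 5.2e-16; adjusted p = 0.53 with an estimated correlation. The 5 that rose, looked up after the values were seen, were a pair of cyclin-dependent kinase inhibitors, which restrain division, a DNA polymerase epsilon subunit, a kinesin light chain-related protein and a putative reverse transcriptase. Of 248 cell wall models 10 rose and 44 fell, 76 when adjusted over the list alone, with a median of -0.74 and a camera adjusted p of 0.0020 (adjusted p = 0.53 with an estimated correlation). Arabinogalactan protein 31 (evm.model.09.6) fell by 3.59 and xyloglucan endotransglucosylase protein 6 (evm.model.10.1534), which remodels walls in growing cells, fell by 1.57 (edgeR adjusted p = 0.056). Of 111 cytosolic ribosomal protein models 2 rose and 8 fell, 1 when adjusted over the list alone, with a median of -0.46 and a camera adjusted p of 6.8e-08 (adjusted p = 0.53 with an estimated correlation). A model that rose in that list, evm.model.03.72, is named uL1c, a plastid ribosomal protein.

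**Figure D2:**
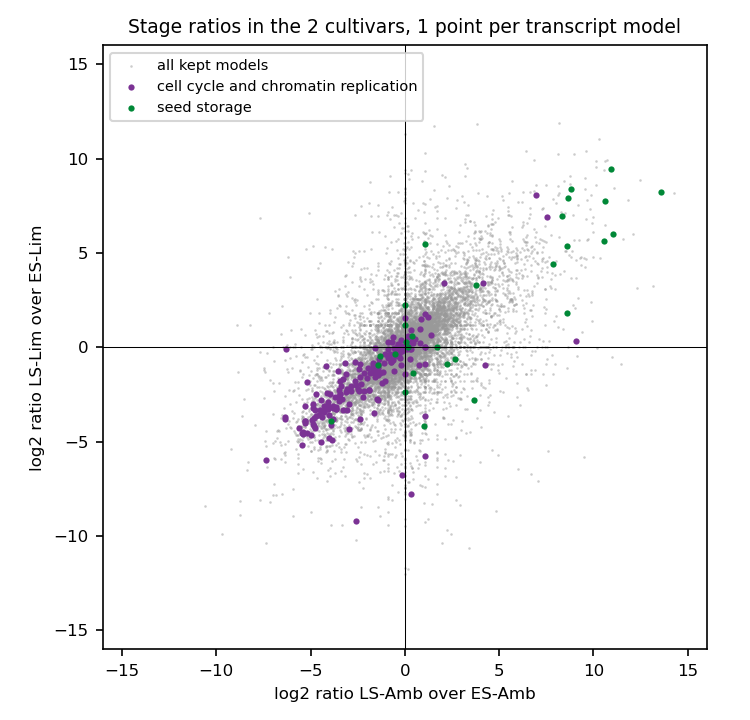
Stage ratios of the 17154 kept models in the 2 cultivars. The x axis is log2 of LS-Amb over ES-Amb, the y axis is log2 of LS-Lim over ES-Lim, grey points are all kept models, purple points the cell cycle and chromatin replication list and green points the seed storage list; the medians were -1.77 and -1.44 for cell cycle and 2.21 and 1.16 for seed storage.

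Chlorophyll a-b binding protein 151 (evm.model.04.2177), an antenna protein, rose by 1.95 (SE 0.21, limma adjusted p = 0.031), from 104503 and 151706 to 415058 and 574086. Of 59 photosynthesis models 3 rose and 0 fell, 2 when adjusted over the list alone, with a median of 0.41 and a camera adjusted p of 0.0181 (adjusted p = 0.53 with an estimated correlation). Sucrose synthase 2 (evm.model.07.374), which splits sucrose, rose by 1.83 (SE 0.12, limma adjusted p = 0.023), and the inactive beta-amylase 9 (evm.model.07.503) by 2.05. Of 50 sugar and starch models 10 rose and 0 fell, 13 when adjusted over the list alone, with a camera adjusted p of 0.0322 (adjusted p = 0.53 with an estimated correlation). Of 50 senescence and nutrient recycling models 7 rose and 2 fell, 11 when adjusted over the list alone, with a camera adjusted p of 0.0181 (adjusted p = 0.53 with an estimated correlation). The cysteine protease RD19B (evm.model.01.2964), the most abundant of these, stood at 52804 and 72497 early and at 105538 and 131096 late without passing.

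Hormone lists held members of either direction. Gibberellin 2-beta-dioxygenase 1 (evm.model.02.2487), which inactivates gibberellins, rose by 2.52 (SE 0.21, limma adjusted p = 0.024), and the gibberellin receptor GID1C (evm.model.06.1381) rose by 0.81 (edgeR adjusted p = 0.061). Of 18 gibberellin models 4 rose and 1 fell, 7 when adjusted over the list alone. Of 105 auxin models 9 rose and 10 fell, 22 when adjusted over the list alone; the most abundant, auxin-repressed 12.5 kDa protein (evm.model.09.548), stood at 132838 and 222991 early and at 280150.0 and 383607 late. Of 107 ethylene models 16 rose and 6 fell, 24 when adjusted over the list alone. ETHYLENE INSENSITIVE 3-like 1 (evm.model.02.129), a transcription factor of ethylene signalling, rose by 1.24 (SE 0.16, limma adjusted p = 0.035; edgeR adjusted p = 0.054).

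Transcription factor models rose or fell in several families. NAC domain-containing protein 2 (evm.model.01.1443) rose by 3.45 (SE 0.13, limma adjusted p = 0.023), from 1670.5 and 1913 to 18307 and 20790, NAC transcription factor 56 (evm.model.02.2283) by 3.83 and NAC domain-containing protein 72 (evm.model.02.2282) by 2.68; NAC factors are known in stress and senescence. Of 41 NAC models 7 rose and 0 fell, 7 when adjusted over the list alone, and of 36 WRKY models, a family of defence and stress regulators, 5 rose and 0 fell, 10 when adjusted over the list alone. Camera adjusted p-values were 0.0299 for NAC and 0.011 for WRKY, each with adjusted p = 0.53 with an estimated correlation. The probable WRKY transcription factor 69 (evm.model.10.1292) rose by 1.60 (SE 0.18). Of 97 MYB models 10 rose and 7 fell, 17 when adjusted over the list alone, with a median of 0.22, a mean of -0.07 and camera pointing up; MYB44-like (evm.model.01.1684) rose, from 5029 and 3942 to 19330 and 16354, and MYBS3 (evm.model.02.2897) by 1.77. Of 55 bHLH models 2 rose and 9 fell, 17 when adjusted over the list alone, and of 86 AP2/ERF models 11 rose and 6 fell, 20 when adjusted over the list alone. Of 23 HD-ZIP models 2 rose and 4 fell, 8 when adjusted over the list alone. In the MADS-box list, which specifies floral organs, 0 of 30 models passed, with 0 when adjusted over the list alone and a camera adjusted p of 0.0519; agamous-like MADS1 (novel_model_7394_5bd9a17a) stood at 2609.6 and 5320.4 early and at 1441 and 3153 late. Its next most abundant members, APETALA 2 and ULTRAPETALA 1, are floral regulators without a MADS box.

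Seed storage models had the highest list median, and embryo and dehydration proteins the next. Late embryogenesis abundant (LEA) proteins protect drying seeds, and LEA protein 2 models evm.model.02.3112 and evm.model.02.3111 rose by 4.25 and 7.80 (limma adjusted p = 0.023 for each). Dehydrin Rab18-like (evm.model.04.2050), a water-stress protein, rose by 5.74 (SE 0.82, limma adjusted p = 0.039; edgeR adjusted p = 0.074), from 773 and 6258 to 117671 and 117353. Of 56 models in the abscisic acid, dehydration and embryo protein list 16 rose and 2 fell, 27 when adjusted over the list alone, with a median of 1.22 and a camera adjusted p of 0.0017 (adjusted p = 0.53 with an estimated correlation). Of 24 seed storage models 9 rose and 1 fell, 12 when adjusted over the list alone, with a median of 3.41 and a camera adjusted p of 0.011 (adjusted p = 0.53 with an estimated correlation). Edestin 3 (evm.model.04.2410), the main hemp seed globulin type, rose by 8.53 (SE 1.40, limma adjusted p = 0.046; edgeR adjusted p = 0.083), with 49207 in LS-Amb and 971 in LS-Lim. The seed storage model that fell is a lipid transfer domain protein (evm.model.02.2351) and also counted in the cuticle list.

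Of 96 heat shock models 17 rose and 5 fell, 36 when adjusted over the list alone, with a median of 0.57 and a camera adjusted p of 0.0017 (adjusted p = 0.53 with an estimated correlation); the most abundant, heat shock cognate protein 80 (evm.model.08.57), a chaperone, stood at 107633 and 93079.9 early and at 169452 and 215291 late without passing. Of 208 pathogenesis-related and defence models 27 rose and 11 fell, 42 when adjusted over the list alone, and the limma camera test did not call the list (adjusted p = 0.28). Major allergen Pru av 1 (evm.model.07.392), a PR-10 type protein, rose by 4.65 (SE 0.58, limma adjusted p = 0.034; edgeR adjusted p = 0.059), and glucan endo-1,3-beta-glucosidase 12 (evm.model.10.1262) fell by 1.80 (edgeR adjusted p = 0.057). Of 127 ABC and other transporter models 17 rose and 9 fell, 31 when adjusted over the list alone, and the limma camera test did not call the list (adjusted p = 0.232). The ABC transporter C family member 2 (evm.model.09.1402) rose by 1.28 and the auxin exporter ABC transporter B family member 19 (evm.model.10.2153) fell by 1.77. Of 20 pollen and anther models 0 rose and 4 fell, 4 when adjusted over the list alone, and of 43 root and xylem models 1 rose and 3 fell, 1 when adjusted over the list alone.

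The models with the highest rises past the threshold were isocitrate lyase (evm.model.10.1503), a vicilin of seed storage (evm.model.01.954), LEA protein D-29 (evm.model.07.285) and a defensin Ec-AMP-D1-like (novel_model_5969_5bd9a17a), by 11.22, 10.91, 10.67 and 10.66. Of these, edgeR placed isocitrate lyase at an adjusted p of 0.066 and the vicilin at 0.055. An oleosin (evm.model.05.2086), an oil body protein, went from 3.43 and 2.46 to 8557 and 2430.0. Those that fell furthest included a stearoyl-[acyl-carrier-protein] 9-desaturase (evm.model.01.1108), from 1540 and 1598 to 0 and 3.72, glycine-rich protein 5-like (evm.model.04.2308), from 2315 and 5177 to 4.47 and 17.4, and peroxidase 40 (evm.model.07.327), from 944 and 2149 to 5.59 and 6.20. A fitted change of a model near 0 depends on the pseudocount.

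Over both cultivars, limma called 1197 models that rose and 1128 that fell of 15694 tested, with 1 residual degree of freedom, so that the stage by cultivar difference stood for the error. DESeq2 called 2297 higher and 2118 lower late, and the edgeR quasi-likelihood test 649 and 681, of which 1319 were among the limma calls. Camera called 11 of the 33 lists, 8 up and 3 down, and 0 with an estimated correlation, which rests on that same degree of freedom (smallest adjusted p = 0.53). The fry rotation test called 0 of 33 for a shared direction and 31 for change in either direction. Its smallest adjusted p for a shared direction, by rotation, was 0.105.

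**Figure D3:**
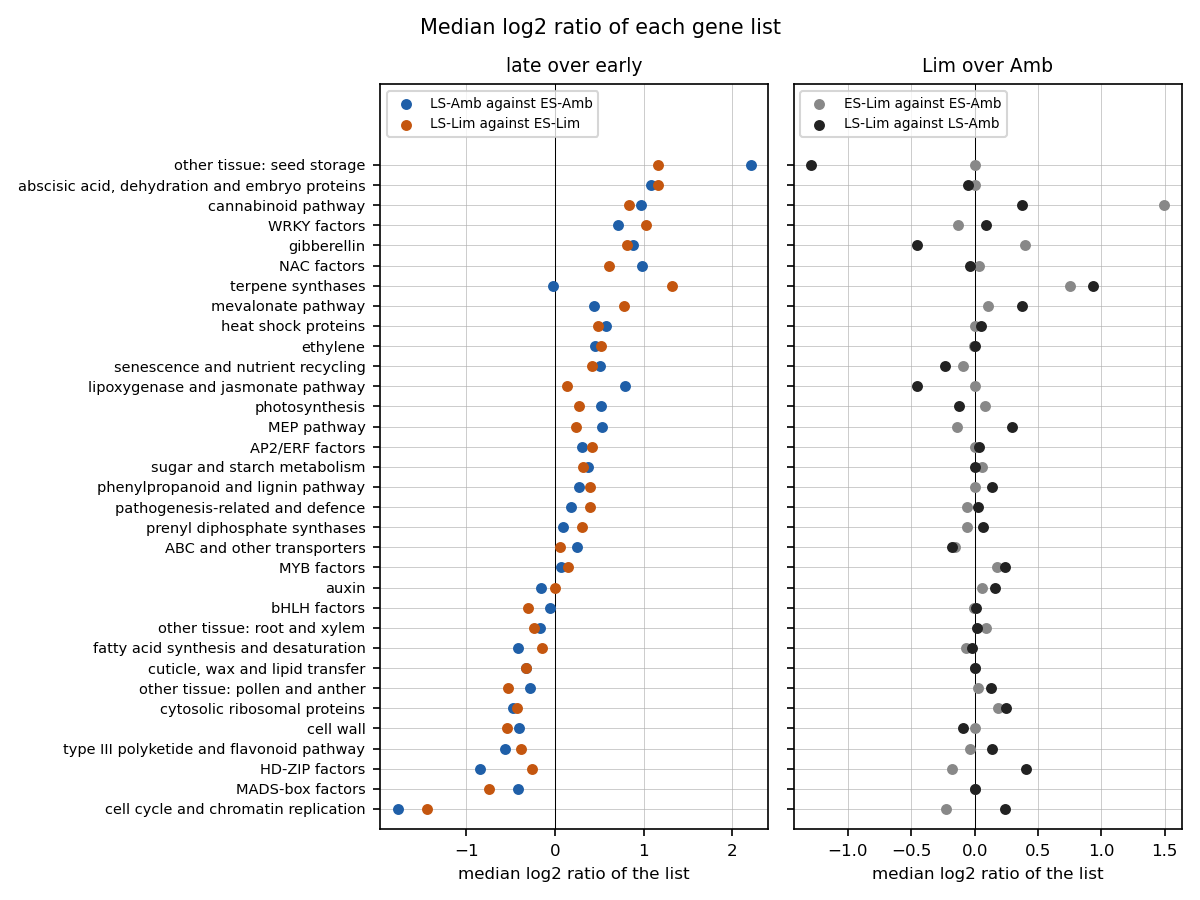
Median log2 ratio of each of the 33 gene lists. The x axes are log2 ratios, late over early on the left (blue Amb, orange Lim) and Lim over Amb on the right (grey ES, black LS); the lowest late-over-early medians were those of cell cycle, -1.77 in Amb and -1.44 in Lim, and the cannabinoid list stood at 1.496 for ES-Lim over ES-Amb.

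Within Amb, late flowers were set against early flowers to ask which stage differences that cultivar showed. Seed storage and LEA models were among the highest ratios. Isocitrate lyase (evm.model.10.1503), an enzyme of the glyoxylate cycle, stood at 0 in ES-Amb and 19577 in LS-Amb, at least 7602-fold higher. Vicilin (evm.model.01.954) was 26118-fold higher (4687 to 1031640.0), from 0.858 to 22420, LEA protein D-29 (evm.model.07.285) 9042-fold higher (2503 to 74670.2) and prunin 1 (evm.model.04.2409), an 11S storage globulin, 5954-fold higher (2735 to 16227). The cannabidiolic acid synthase precursor (evm.model.09.1091) was 795-fold higher (482 to 1421).

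Also high in LS-Amb were embryonic protein DC-8 (evm.model.03.1085), at 9162 and at least 3558-fold above ES-Amb, a LEA domain-containing protein (evm.model.01.3041), at least 1411-fold higher, a CER1-like aldehyde decarbonylase (novel_model_1858_5bd9a17a) of wax synthesis, at least 1728-fold higher, and the desaturase/conjugase FADX (evm.model.06.1707), 4247-fold higher (1453 to 20599). Lowest against ES-Amb were the stearoyl-[acyl-carrier-protein] 9-desaturase evm.model.01.1108, at least 459-fold lower, a stress-response A/B barrel protein (evm.model.ctgX11.14), at least 248-fold lower, and the GRAS factor scarecrow-like protein 32 (evm.model.04.1749), from 1252 to 1.12. The cytokinesis syntaxin KNOLLE (evm.model.07.901) went from 476 to 0, at least 142-fold lower, and a Tricorn protease model from 455 to 0. An exopolygalacturonase-like pectin hydrolase (evm.model.10.1007) was 796-fold lower (142 to 31457), UDP-glycosyltransferase 91C1 (evm.model.ctgX7.15) 741-fold lower (133 to 29304) and glycine-rich protein 5-like (evm.model.04.2308) 518-fold lower (202 to 1902).

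List medians for LS-Amb over ES-Amb are given with their percentile among 10000 random lists matched on mean expression, as a description of these libraries. Of 186 cell cycle models 14 were at least 2-fold higher and 115 lower, with a median of -1.77 (percentile 0). The seed storage list had a median of 2.21 (percentile 100), or 3.70 with values under 3 reads set to 3 reads, with 18 of 29 models higher. The cannabinoid list had a median of 0.98 (percentile 96.4), or 1.65 at that bound, with 5 models higher and 3 lower. The lipoxygenase list stood at 0.79 (percentile 99.99), NAC factors at 0.99 (percentile 99.95), WRKY factors at 0.72 (percentile 99.8), HD-ZIP factors at -0.85 (percentile 0.02) and the flavonoid list at -0.57 (percentile 0.02). Across all kept models 7416 were past 2-fold, 3993 higher and 3423 lower, with 906 unchanged models past 2-fold in a simulation of counting error alone. Under total count scaling the median of all models was -0.08 and higher models were 47.5% of those past 2-fold against 53.8%; a pseudocount of 1 CPM gave 41.9%.

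Within Lim, late flowers were set against early flowers in the same way. The highest ratios included a defensin and a LEA protein. An F-box/kelch-repeat protein (evm.model.04.231) stood at 0 in ES-Lim and 3393 in LS-Lim, at least 1378-fold higher, and the calmodulin-binding type protein IQM3 (evm.model.04.108) at 0 and 2545, at least 1034-fold higher. Patatin-like protein 2 (evm.model.08.261), a lipid acyl hydrolase, was 2170.2-fold higher (600.2 to 17928). The cannabidiolic acid synthase precursor (evm.model.09.1091) was 511-fold higher (376 to 712). Ferredoxin--NADP reductase, root isozyme (evm.model.08.1972), an enzyme of non-green plastids, went from 4089 to 0, at least 1099-fold lower.

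Others high in LS-Lim were the antimicrobial peptide defensin Ec-AMP-D1-like (novel_model_5969_5bd9a17a), at least 856-fold higher, an LRR receptor-like kinase (novel_model_2005_5bd9a17a), at least 557-fold higher, a probable amidase (evm.model.01.1010), at least 507-fold higher, the 11 kDa LEA protein (evm.model.10.480), 1577-fold higher (616 to 5791), and anthocyanidin 3-O-glucosyltransferase 2 (evm.model.08.1863), at least 398-fold higher. MEN-8 (evm.model.05.827) went from 7783 to 1.24, 6278-fold lower (1126 to 247985), and protein M7 (evm.model.05.1884) from 7348 to 1.24, 5927-fold lower (1064 to 234128). Cytochrome P450 CYP94D108-like (evm.model.07.1819) was 1878-fold lower (804 to 5784), whereas in Amb it was 10.6-fold higher late (9.87 to 11.5). Fasciclin-like arabinogalactan protein 21 (evm.model.04.1157) was at least 359-fold lower, 3-ketoacyl-CoA synthase 19 (evm.model.02.759) at least 315-fold lower and a polygalacturonase inhibitor-like protein (evm.model.10.537) at least 254-fold lower.

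For LS-Lim over ES-Lim the cell cycle list had a median of -1.44 (percentile 0), with 8 models at least 2-fold higher and 108 lower of 186. The terpene synthase list stood at 1.32 (percentile 99.6) with 9 higher and 5 lower of 17, against -0.02 in Amb, or -0.22 there under total count scaling; the probable monoterpene synthase MTS1 (evm.model.07.850) was 33.6-fold higher (26.9 to 42.6). The cannabinoid list stood at 0.83 (percentile 95.5), WRKY factors at 1.03 (percentile 100) and the seed storage list at 1.16, or 3.60 with values under 3 reads set to 3 reads. The lipoxygenase list stood at 0.14 (percentile 81.1), or 0.41 at single-model loci, 0.23 with values of at least 10 and 0 under total count scaling. NAC factors stood at 0.61 (percentile 99.8), HD-ZIP factors at -0.26 (percentile 5.42) and the flavonoid list at -0.39 (percentile 0.68); total count scaling gave 0.38, -0.46 and -0.62, and single-model loci gave 0.35 for NAC factors. Lists with medians that changed sign under total count scaling were transporters, from 0.06 (0.000779 with the list as first written) to -0.14 in this comparison, and prenyl diphosphate synthases, from 0.09 to -0.11 in LS-Amb over ES-Amb. In all, 7445 models were past 2-fold, 3716 higher and 3729 lower, with 774 unchanged models past 2-fold in the simulation. Under total count scaling the median of all models was -0.16 and higher models were 43.1% against 49.9%; a pseudocount of 1 CPM gave 39.2%.

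Both stage ratios went the same way for 4447 models past 2-fold, 2221 higher and 2226 lower, where independent lists of those sizes would share 865 and 744. The split depended on the setting, with 1891 higher and 2623 lower under total count scaling and 1195 higher and 1904 lower with a pseudocount of 1 CPM. Opposite directions were found for 513 models, where independent lists would give 1609.5. Across models the ratios had a Pearson correlation of 0.59 and a Spearman correlation of 0.60, and models are not independent replicates.

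At the early stage, Lim was set against Amb to ask which transcripts differed between cultivars at that stage. Geranyltransferase models differed in either direction. The geranylpyrophosphate:olivetolate geranyltransferase model novel_model_1811_5bd9a17a stood at 523 in ES-Lim and 54.1 in ES-Amb, 9.67-fold higher (7.45 to 12.7), and novel_model_1812_5bd9a17a at 139 and 1.72, 80.8-fold higher (22.02 to 673). Both models share a description and a best hit, and whether they belong to the same gene was not tested. In the other direction, evm.model.01.1974 was 2.41-fold lower in ES-Lim (2.20 to 2.64) and novel_model_1814_5bd9a17a 1.32-fold lower (1.25 to 1.39). The cannabidiolic acid synthase precursor (evm.model.09.1091) was 2.61-fold higher (1.42 to 5.08) at 33.6.

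Of the 10 cannabinoid models 6 were at least 2-fold higher in ES-Lim and 1 lower. Among those higher, cannabidiolic acid synthase-like 1 (evm.model.09.1318) had 6 reads against 1 and the olivetolic acid cyclase model 11 against 2. The 5 further pathway models, chosen after their values were seen, had a median of 0.14 (percentile 81.0), with 0 higher and 0 lower. The cannabinoid list median was 1.496 (percentile 99.9 among 10000 random lists matched on mean expression), or 1.16 with values under 3 reads set to 3 reads. The terpene synthase list stood at 0.75 (percentile 99.0), or 0.35 at that bound, with 8 higher and 7 lower of 17; myrcene synthase (evm.model.05.137) was 52.4-fold higher (23.8 to 144) and terpene synthase 29 (evm.model.10.1522) 8.65-fold lower (7.03 to 10.7). Cell cycle models had a median of -0.23 (percentile 0), ribosomal proteins 0.18 (percentile 99.99), MYB factors 0.18 (percentile 99.3) and transporters -0.15 (percentile 0.03), or -0.12 with the transporter list as first written. For comparison with LS, the lipoxygenase list stood at 0 (percentile 53.02), HD-ZIP factors at -0.18 (percentile 3.62) and senescence models at -0.09 (percentile 5.20).

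The highest ratios in ES-Lim were of models near 0 elsewhere, ferredoxin--NADP reductase, root isozyme (evm.model.08.1972) at least 1588-fold, protein M7 (evm.model.05.1884) at least 2853-fold and MEN-8 (evm.model.05.827) 9067-fold (1627 to 358166). Models high in both Lim libraries were a mitochondrial carrier protein (evm.model.02.2628), at least 1369-fold, an RPP13-like disease resistance protein (evm.model.03.49), at least 1225-fold, a UPF0481 protein (evm.model.09.251), at 4784 against 0.858, and NUCLEAR FUSION DEFECTIVE 2 (evm.model.03.434), at least 808-fold. Cytochrome P450 71D11 (evm.model.08.129) was at least 651-fold higher. Lowest in ES-Lim were a galacturonosyltransferase-like 3 of pectin synthesis (novel_model_7030_5bd9a17a), 4511-fold (809 to 178229), a pathogen-related protein (evm.model.01.1964), 2232-fold (617 to 18433), a phosphodiesterase (evm.model.02.1317), 2091-fold (375 to 82628), and the ESCRT-related protein CHMP1B (evm.model.08.984), a membrane sorting component, 1255-fold (489.7 to 4607). The F-box/kelch-repeat protein At5g26960 (evm.model.06.946) was 1836-fold lower (329 to 72547), a retrovirus-related Pol polyprotein (evm.model.08.291) 1639-fold lower (294 to 64780.3) and patatin-like protein 1 (evm.model.04.1904) 1281-fold lower (229.5 to 50651), each at 1 read in ES-Lim, while F-box/kelch-repeat protein At1g23390 (evm.model.04.231) went from 402 to 0 and the corepressor TOPLESS (evm.model.10.13) from 580.3 to 0. In all, 4020 models were past 2-fold, 2254 higher and 1766 lower, with 548 unchanged models past 2-fold in the simulation.

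The pollen and anther list fixed beforehand had a median of 0.03 for ES-Lim over ES-Amb (percentile 71.5), with 4 of 22 models at least 2-fold higher and 0 lower. Some anther transcripts stood higher in ES-Lim, as read from a tapetum and pollen wall list of 24 models, written after the highest and lowest models of each comparison were seen and holding none of those. Tetraketide alpha-pyrone reductase 1 (evm.model.01.148), an enzyme of the pollen wall polymer, stood at 0.858 in ES-Amb and 549 in ES-Lim, and ABORTED MICROSPORES-like (evm.model.01.509), a tapetum regulator, at 1.72 and 779.6. The tapetum and pollen wall list had a median of 0.55 (percentile 99.8), with 11 models at least 2-fold higher and 3 lower.

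**Figure D4:**
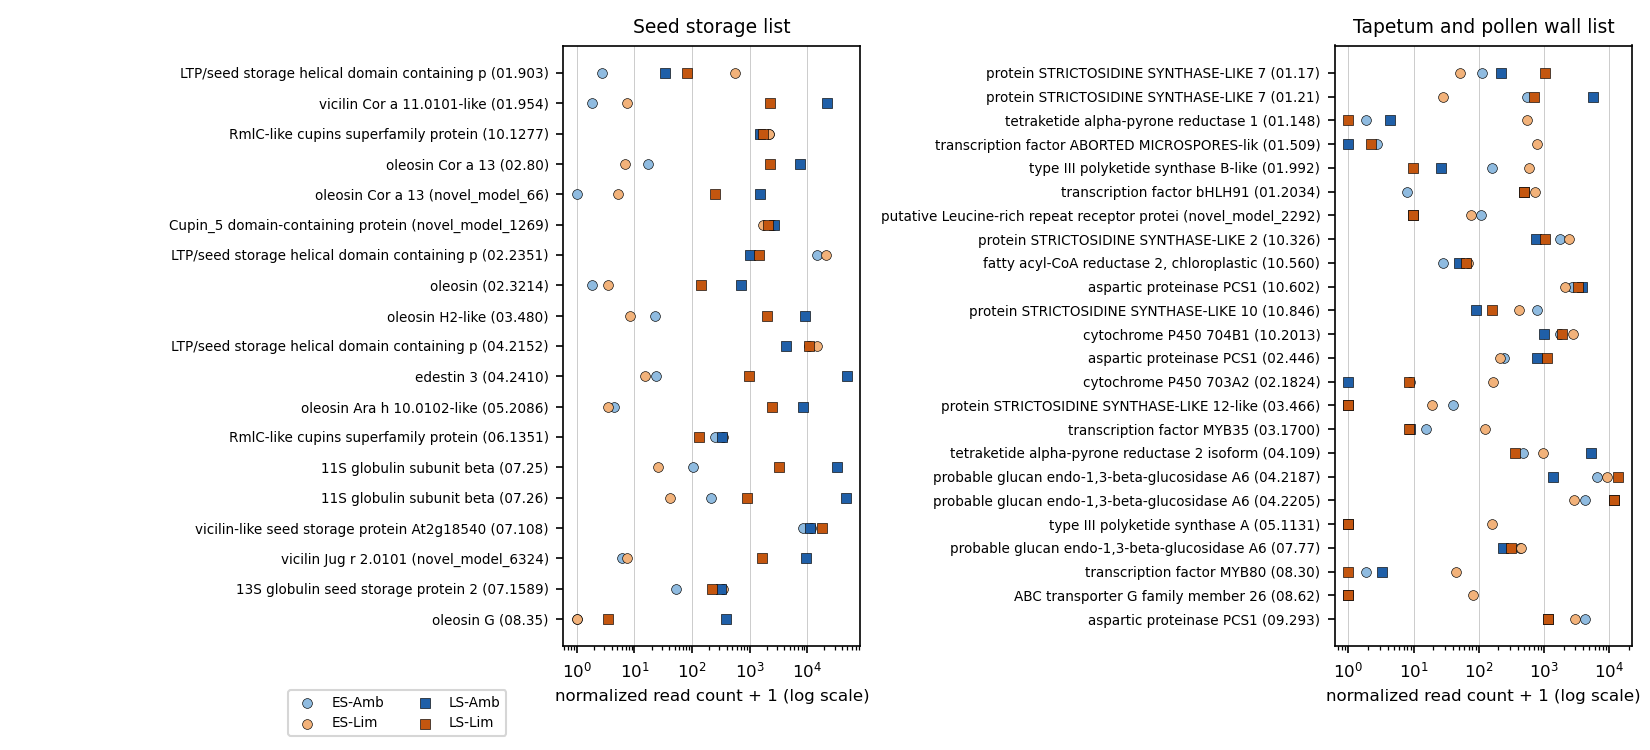
Levels of seed storage and anther models in each library. The x axes are normalized read counts plus 1 on a log scale, the left panel shows seed storage list members of at least 100 in any library and the right panel the tapetum and pollen wall list, with circles for ES, squares for LS, blue for Amb and orange for Lim; edestin 3 stood at 49207 in LS-Amb and 971 in LS-Lim, and tetraketide alpha-pyrone reductase 1 at 549 in ES-Lim.

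At the late stage, Lim was set against Amb to ask which transcripts differed between cultivars in late flowers. Several seed storage transcripts were lower in LS-Lim. Edestin 3 (evm.model.04.2410) was 50.7-fold lower (47.2 to 54.5), 11S globulin subunit beta (evm.model.07.26) 53.9-fold lower (50.1 to 58.1) and prunin 1 (evm.model.04.2409) 55.6-fold lower (50.6 to 61.2), all storage globulins. The prenyltransferase models novel_model_1811_5bd9a17a and novel_model_1812_5bd9a17a were again higher in Lim, 24.4-fold (17.2 to 35.7) and 32.8-fold (15.6 to 82.6). The cannabidiolic acid synthase precursor (evm.model.09.1091) was 1.68-fold higher in LS-Lim (1.64 to 1.72), and the polyketide synthase 4 model novel_model_7345_5bd9a17a, chosen after its values were seen, was 3.44-fold higher (3.39 to 3.50).

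Of 29 seed storage models 5 were at least 2-fold higher in LS-Lim and 16 lower, with a median of -1.29 (percentile 0 among 10000 random lists matched on mean expression), or -1.76 with values under 3 reads set to 3 reads. The lipoxygenase list stood at -0.46 (percentile 0), with 4 higher and 13 lower of 51; linoleate 9S-lipoxygenase 5 (evm.model.03.146) was 4.37-fold lower (4.28 to 4.46). The terpene synthase list stood at 0.94 (percentile 99.7), with 8 higher and 3 lower, and the monoterpene synthase MTS1 (evm.model.07.850) was 4.85-fold higher (4.36 to 5.42). The cannabinoid list stood at 0.37 (percentile 90.6), or 0.75 at that bound, with 4 higher and 0 lower. Cell cycle models had a median of 0.24 (percentile 100), ribosomal proteins 0.25 (percentile 100), HD-ZIP factors 0.40 (percentile 99.7), MYB factors 0.24 (percentile 99.8), senescence models -0.24 (percentile 0.60) and transporters -0.18 (percentile 0.13), or -0.07 with the transporter list as first written. The bHLH list crossed 0, from 0.011 to -0.0023 under total count scaling.

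The highest ratios in LS-Lim were of IQM3 (evm.model.04.108), at least 759-fold, a probable amidase (evm.model.01.1010), 1117-fold (200.03 to 44164), soyasapogenol B glucuronide galactosyltransferase-like (evm.model.01.68), an enzyme type of saponin synthesis, at least 444-fold, and a UPF0481 protein (evm.model.09.251), at least 459-fold. MLO protein homolog 1-like (evm.model.08.1983), of a family tied to powdery mildew susceptibility, was at least 204-fold higher, auxin-induced protein PCNT115-like (evm.model.07.641) at least 192-fold and class V chitinase CHIT5-like (evm.model.08.1943) at least 179.7-fold higher. Lowest in LS-Lim were a Tol-Pal beta propeller protein (evm.model.01.2771), at least 2753-fold, U-box protein 43 (novel_model_2350_5bd9a17a), 2227-fold (399 to 87985), CYP94D108-like (evm.model.07.1819), 1148-fold (492 to 3536), cytidine deaminase 1 (evm.model.02.1315), at least 944-fold, and embryonic protein DC-8 (evm.model.03.1085), 568-fold (332 to 1068). Galacturonosyltransferase-like 3 (novel_model_7030_5bd9a17a) was at least 404-fold lower, receptor-like protein 6 (novel_model_2352_5bd9a17a) at least 252-fold, cytochrome P450 94A2 (evm.model.04.2444) at least 237-fold and EARLY FLOWERING 5 (novel_model_836_5bd9a17a) at least 149.9-fold. In all, 5422 models were past 2-fold, 2662 higher and 2760 lower, with 1114 unchanged models past 2-fold in the simulation.

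Some models were high in one cultivar and near 0 in the other at both stages. With at least 100 in both libraries of a cultivar and at most 3 reads in both of the other, 24 models were high in Lim and 20 in Amb. For the RPP13-like protein (evm.model.03.49), a disease resistance type, the levels were 0 and 0 in Amb and 3155 and 937 in Lim. For galacturonosyltransferase-like 3 (novel_model_7030_5bd9a17a) they were 3702 and 1502 in Amb and 0.821 and 0 in Lim. Limma called 0 of 15694 models for cultivar, with 1718 at an unadjusted p under 0.05 and a smallest adjusted p of 0.18; limma-voom and the edgeR quasi-likelihood test also called 0 (1914 and 1408 at an unadjusted p under 0.05), and DESeq2 called 413 higher in Lim and 314 lower. In simulated data limma recovered 72 of 100 planted 4-fold cultivar differences at a dispersion of 0.1, and 24 of 100 at 0.2, near the 0.199 that edgeR estimated from these libraries. At 0.2 it recovered 98 of 100 planted 16-fold cultivar differences. The simulation gave every model the same dispersion and planted no stage by cultivar difference, so it does not explain why limma called 0 here. With models of any count in the fit, limma called 1, the hypothetical protein evm.model.02.385, at 793 and 989 in Amb against 44040.2 and 68927 in Lim (adjusted p = 0.032).

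When adjusted over the list alone, limma called 2 of 10 cannabinoid models for cultivar, 2 fatty acid models, 1 lipoxygenase model and 1 heat shock model, and 0 in each of the other 29 lists; over all genes tested, none of these passed. Looked up after the values were seen, the cannabinoid models called by limma were novel_model_1811_5bd9a17a, higher in Lim by 3.91 (SE 0.60, adjusted p = 0.024 over the list alone, 0.301 over all), and novel_model_1812_5bd9a17a, by 5.28 (SE 0.77, adjusted p = 0.024 over the list alone, 0.298 over all). Those models share a best hit, so they may not count as separate pathway members. The others were a stearoyl-[acyl-carrier-protein] 9-desaturase (evm.model.02.2485), at 541 and 192 in Amb and 0 in Lim, 3-ketoacyl-CoA synthase 11 (evm.model.08.758), an elongase of long fatty acids, higher in Lim by 1.81, linoleate 9S-lipoxygenase 5 (evm.model.07.1781), at 58.4 and 12.3 in Amb and 2212 and 1123 in Lim, and the chloroplast chaperone dnaJ 11 (evm.model.01.1017), higher in Lim by 2.82. Camera called 1 list, cytosolic ribosomal proteins, up in Lim (adjusted p = 3.7e-04), and adjusted p = 0.96 with an estimated correlation; fry called 0 of 33 (smallest adjusted p = 0.365).

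Cultivar ratios went the same way at both stages for 1555 models past 2-fold, 864 higher and 691 lower in Lim, where independent lists would share 350 and 284. Opposite directions were found for 635, where independent lists would give 637. Across models the Pearson correlation was 0.31 and the Spearman correlation 0.25. The stage log2 ratio of Lim lay more than 2 above that of Amb for 1224 models and more than 2 below it for 1518; with 1 library per group this difference had no test. Heat shock 70 kDa protein 1 (evm.model.05.1253), a chaperone, was 1.30-fold higher late in Amb (1.29 to 1.31) and 4.92-fold higher late in Lim (4.86 to 4.98), while its neighbour evm.model.05.1254 was 1.27-fold higher (1.25 to 1.29) and 1.98-fold lower (1.96 to 2.01).

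The authors' own comparisons, made with DESeq on 1 library against 1, list adjusted p-values that compare libraries, not conditions. At an adjusted p under 0.05 their tables held 219 models higher and 148 lower in LS-Amb against ES-Amb, 174 and 79 in LS-Lim against ES-Lim, 57 and 49 in ES-Lim against ES-Amb, and 28 and 36 in LS-Lim against LS-Amb, and each of these was past 2-fold. The cannabidiolic acid synthase precursor (evm.model.09.1091) had a deposited adjusted p of 1.9e-08 in Amb and 1.7e-07 in Lim for late against early.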

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

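For the seed pattern, the test on members near 0 in the early libraries and the test of scaling against random lists were chosen only after the result was seen. Several seed storage transcripts were more abundant in LS-Amb than in LS-Lim, with edestin 3 (evm.model.04.2410) at 49207 against 971 and 11S globulin subunit beta (evm.model.07.26) at 47654 against 884. Developing seeds among the LS-Amb flowers are a hypothesis. Seed transcripts also stood above early levels in Lim, with vicilin (evm.model.01.954) at 6.57 in ES-Lim and 2309 in LS-Lim. The second embryo list had a median of 2.21 (percentile 100) for LS-Lim over ES-Lim, with 17 of 26 models at least 2-fold higher and 2 lower. Seeds in both late libraries would bear on the late over early differences and were not tested. The test written beforehand on a second embryo list gave a median log2 ratio of 0.15 (percentile 88.7) for LS-Amb over LS-Lim, which met the bound set for rejecting seeds. Only after that result was seen was the bound judged unsuited to this list. The reason was that 16 of the list's 26 members stood at 100 or more in an early library, perhaps from other tissue (not tested). Its 10 members near 0 early had a median of 1.205, with 7 of 10 higher in LS-Amb, short of the share asked for. That shortfall turned on a member at the floor, LEC2 (evm.model.09.569), at 0 in LS-Amb and 3.72 in LS-Lim. The other members not higher in LS-Amb were 11-beta-hydroxysteroid dehydrogenase models. Seeds could therefore be present but this is open. Library scaling was argued against by the seed storage list, at percentile 0 for LS-Lim over LS-Amb among matched random lists, which a factor per library moves alike. Its median of 1.29 under the other scalings met the bound written beforehand for rejecting scaling, but those scalings differed too little here to test it. A general abscisic acid or dehydration response stays open: the abscisic acid genes had a median of -0.0706, which met the bound written beforehand for rejecting it. Only after that result was seen was the bound set aside, since 5 of 22 genes were at least 2-fold higher in LS-Amb and 2 lower, too wide a spread for a median to decide.

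For the anther pattern, the near-0 test and both scaling tests were chosen only after the result was seen. Tapetum transcripts such as ABORTED MICROSPORES-like (evm.model.01.509), at 1.72 in ES-Amb and 779.6 in ES-Lim, stood higher in ES-Lim, and anthers or male flowers among the ES-Lim flowers are a hypothesis. The pollen and anther list fixed beforehand had a median log2 ratio of 0.03 (percentile 71.5). The tapetum list of 24 had a median log2 ratio of 0.55, between the bounds written beforehand, with 13 members at 100 or more in a late library. Among these was a glucanase A6 (evm.model.04.2187), at 6576 in ES-Amb, 9171 in ES-Lim, 1355 in LS-Amb and 13952 in LS-Lim. Another glucanase A6 (evm.model.04.2205) stood at 4250 in ES-Amb, 2908 in ES-Lim, 11866.5 in LS-Amb and 12058 in LS-Lim. The 11 list members near 0 in both late libraries had a median of 4.25, with 9 of 11 higher in ES-Lim, which may point to anther tissue. Library scaling was argued against by the whole tapetum list, at percentile 99.8 among matched random lists, which a factor per library moves alike. The near-0 median was also 4.25 under the other scalings, but these differed too little here to test it. For LS-Lim over ES-Lim the tapetum list had a median of -1.38 (percentile 0.01), with 4 of 24 models at least 2-fold higher and 14 lower. Anther tissue in ES-Lim would also bear on the late over early differences in Lim and this was not tested. A difference in anther timing between cultivars stays open.

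Stage log2 ratios of several named models, taken with the pseudocount, went opposite ways in the cultivars, and the difference was not tested. The stage log2 ratio of Lim minus that of Amb was 10.07 for the syntaxin KNOLLE (evm.model.07.901), 7.55 for a pathogen-related protein (evm.model.01.1964), 3.17 for an F-box/kelch-repeat protein (evm.model.06.946), 10.95 for patatin-like protein 1 (evm.model.04.1904), 9.62 for a soyasapogenol B glucuronide galactosyltransferase-like model (evm.model.01.68) and 8.43 for PCNT115-like (evm.model.07.641). It was -14.07 for CYP94D108-like (evm.model.07.1819), -12.38 for fasciclin-like arabinogalactan protein 21 (evm.model.04.1157), -12.33 for a polygalacturonase inhibitor-like model (evm.model.10.537), -5.69 for NUCLEAR FUSION DEFECTIVE 2 (evm.model.03.434), -4.18 for cytidine deaminase 1 (evm.model.02.1315), -7.30 for U-box protein 43 (novel_model_2350_5bd9a17a) and -9.74 for EARLY FLOWERING 5 (novel_model_836_5bd9a17a). Exact 95% intervals for counting error, added after the result was seen, held 1 for 7 of these 13 models in one cultivar, which left the direction open there. In Lim these were KNOLLE (6 early reads against 10 late, late over early 0.829 to 8.43), the F-box/kelch-repeat protein (1 against 3), U-box protein 43 (6 against 1) and cytidine deaminase 1 (5 against 0). In Amb they were PCNT115-like (2 against 0), the galactosyltransferase-like model (6 against 0) and the inhibitor-like model (0 against 4). Where a library had 0 reads the size of the difference depends on the pseudocount.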

How the results depend on the processing

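A 4-fold limit by construction left fewer models: 3764 for LS-Amb against ES-Amb, 3780 for LS-Lim against ES-Lim, 1874 for ES-Lim against ES-Amb, 2086 for LS-Lim against LS-Amb, 2074 shared by stage and 562 shared by cultivar. The larger pseudocount of 1 CPM, by construction, gave 4728, 4716, 1827 and 2167 for those comparisons, 591 shared by cultivar and 821 with a stage by cultivar difference. The stricter filter of at least 1 CPM left 2668 for ES-Lim against ES-Amb, 3147 for LS-Lim against LS-Amb and 1674 for the difference. For stage, DESeq2 called 4415, DESeq2 size factors in edgeR 1352 and edgeR on recovered reads 1330; for cultivar, DESeq2 called 727 and limma with models of any count 1, and the cause was not tested.

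Of all settings, 69 counts were the same, 18 moved and 2 were stronger, and 1149 list medians were the same and 35 moved. For named models, 1131 values were the same, 138 moved and 0 reversed. The 0 reversed does not test the direction of these models. A smaller pseudocount cannot change which library is higher, and the other scalings differed too little to reverse a large ratio. The pseudocount of 1 CPM, the 1 CPM filter, single-model loci, values set to 3 reads, lists as first written, edgeR on recovered reads, limma with TMM and limma without embryo, seed and anther models were added after the result was seen. The 4-fold limit was not run for the stage by cultivar difference, and leaving out 1 library was not run because no residual degree of freedom would be left. No fold is given where both libraries were at or under 3 reads.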

Other observations

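Some transcripts were present in all libraries of a stage and near 0 in the other. With at least 100 in both libraries of a stage and at most 3 reads in both of the other, 24 models were high late and 13 early. A non-specific lipid-transfer protein 1 (evm.model.09.142), of a family that carries lipids to surfaces, stood at 0 and 0 early and at 1659 and 967 late, and a stress-response A/B barrel protein (evm.model.ctgX11.14) at 833 and 949 early and 0 late. Late flowers also carried malate synthase (evm.model.08.1961), the partner of isocitrate lyase in turning stored fat into sugar, at 27605 in LS-Amb and 12361 in LS-Lim against 109 and 865 early, and kunitz type trypsin inhibitor 104 (evm.model.02.2512), a protease inhibitor, at 25333 and 23142 against 427 and 713; both were chosen after their values were seen.

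All tests of the locus pattern were written before its result was seen. Of 5934 loci with 2 or more transcript models or an isoform suffix in a model name, 92.6% were under 100 in every library. The share was 49.96% of the 24670.0 other loci, which had 1 model. Some of the 5934 also held only 1 model, so overlap of models is not shown for each of them. Among ribosomal protein and photosynthesis loci, which every green cell uses, the shares were 95.2% of 126 and 21.4% of 187, a ratio of 4.45. This met the bound written beforehand for reads shared by overlapping models having been left uncounted. The median summed level of ribosomal protein loci in the first class was 0 times that of those with 1 model, whose median was 10121.5. This met the bound written beforehand for rejecting low expression of genes at such loci. Unexpressed gene copies would also give 0 and the same shares, so these tests cannot decide and low expression stays open. How reads were assigned stays open, and genes at such loci, olivetolic acid cyclase among them, could be expressed and not seen.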
